A study of Mus musculus with 9 samples.

How the data were processed

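Gene expression was measured in whole liver of male mice on Clariom S mouse arrays, 9 arrays in all. The labels give 3 groups of 3 mice: wild-type mice given vehicle, leptin-deficient ob/ob mice given vehicle, and ob/ob mice given an extract of the rice bean *Vigna umbellata* by oral gavage at 100 mg per kg body weight. The sample titles name the wild-type mice as C57BL/6JHamSlc-+/+. Treatment lasted 42 days in mice that were 6 weeks old at purchase, and about 100 ng of total RNA per sample entered labelling, per the labels' protocols. Each array was taken to be 1 mouse, the 3 per group that the design text states.

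The authors deposited log2 values, 1 per transcript cluster and array, rounded to 2 decimals and running from 1.86 to 19.93. Per the submitters' processing notes the values were made with Transcriptome Analysis Console 4.0.2 and SST-RMA, a form of robust multi-chip averaging preceded by a transformation that counters the compression of fold changes; differences on this scale therefore depend on that step. The top value was 19.93, and 16 transcript clusters sat at their array's maximum on all 9 arrays, so a change in those could not be read. Detection calls and background signal were not used here, so the detection filter that the design text describes was not applied, and whether a dim gene was above background is not known here. For arrays the number of mice, 3 per group, limits the precision.

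The table held 22206 transcript clusters. GEO's platform annotation gave 19572 of them 1 symbol each (19505 distinct symbols, 55 of them with more than 1 cluster), 0 several symbols and 2634 none. All 19572 Entrez identifiers matched the RefSeq table for assembly GRCm38.p6, which was used for names only and changed 0 symbols. The sources used here name no genome build for the array, so no coordinates are given. All 9 values of 270 clusters were identical to those of another cluster, and such clusters may measure the same sequence.

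Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with a mean per group was fitted over all 9 arrays, so that the 3 groups shared 1 estimate of the spread (6 residual degrees of freedom), and the eBayes step with default settings added 4.45 prior degrees of freedom. This follows the design text, which names an analysis of variance with an empirical Bayes correction. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all clusters. The design text's own criterion, an unadjusted p under 0.05 with a linear fold over 1.1, is given beside it; every cluster under that p also passed the fold limit. The 30 gene lists, which held 606 genes of which 545 were measured, covered metabolic pathways, stress, inflammation, sex-biased and zonal liver genes and markers of other cell types. They were tested with limma's camera (preset inter-gene correlation 0.01, two-sided, 1 cluster per symbol, the one with the highest mean), with adjustment over the 30 lists within each comparison. Whether the extract opposed the ob/ob difference was asked with the correlation and covariance across genes of both sets of changes, beside 1000 simulations of unchanged groups that share the same ob/ob vehicle arrays.

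The genes named in the text follow a rule. In each comparison and direction it takes up to 10 called genes with the largest change among those whose groups did not overlap. Where fewer than 5 passed in a direction, it takes up to 6 with the smallest p among those meeting the design text's criterion without overlap. It adds up to 4 members of each list by smallest p, the leptin gene *Lep*, and, for the comparisons with the extract, the genes named for ob/ob against wild type. Clusters without a single symbol, predicted genes, olfactory and vomeronasal receptors and small RNA genes were left out of the first part. Genes named outside the rule are said to be so. The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

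On simulated data with the real genes' means and spread and known changes, the fit for ob/ob vehicle against wild type recovered 8.96% of 67 clusters changed by 1 log2, 88.1% of 67 changed by 2 and 100% of 66 changed by 4, and it called 12 of 22006 unchanged clusters. For extract against ob/ob vehicle the shares were 10.4%, 74.6% and 98.5%, with 8 unchanged clusters called. For extract against wild type they were 8.96%, 77.6% and 100%, with 8 called. A list shifted by 1 log2 was called in each comparison and 0 of the other 29 lists were. The noise was drawn independently for each gene and array. These list counts therefore do not show how the list test behaves where genes are correlated.

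The groups share replicate numbers, and the labels do not say that a number marks anything. The numbers were checked by correlating the deviations of same-numbered arrays from their group means. Between wild-type and ob/ob vehicle all 3 pairs were over 0.1 (0.256, 0.262 and 0.450), which meets the rule set for pairing in that comparison. The pairing there comes from the values alone, and wild-type vehicle 1 correlated best with ob/ob vehicle 2. Deviations within a group sum to 0, so a pattern shared by the number 3 arrays can by itself raise the other pairs. The check therefore does not settle a pairing. In the other 6 pairs, which involve the extract arrays, 0 were over 0.1 (lowest −0.208). The fit without the block, planned as the main one, was kept, and the fit with the replicate number as a block over all 9 arrays is one of the alternatives. That choice was made after the block's counts of calls had been seen.

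Alternatives were quantile normalization, subtraction of each array's median, leaving out the 30% or 50% of clusters with the lowest mean, eBayes with an intensity trend and with the trend and robust settings, no empirical Bayes step, only the arrays of the groups compared, array weights, the replicate block, an estimated inter-gene correlation, camera on ranks, the mean over the clusters of a symbol, and leaving out each array in turn. After the data were seen, a fit without wild-type vehicle 3 and ob/ob vehicle 3 and a fit with the array's interquartile range as a covariate were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.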

Results

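Liver expression was profiled on 9 arrays, 3 from wild-type mice given vehicle, 3 from ob/ob mice given vehicle and 3 from ob/ob mice given *Vigna umbellata* extract. The ob/ob mouse lacks functional leptin, the adipocyte hormone that limits food intake, and becomes obese with a fatty liver. Array medians lay between 5.07 and 5.36 log2. Within groups the arrays correlated at 0.990 between ob/ob vehicle 1 and 2, at 0.980 between wild-type vehicle 1 and 2, and between 0.982 and 0.987 among the extract arrays. The remaining array of each vehicle group stood apart. Ob/ob vehicle 3 correlated at 0.948 and 0.952 with its group, and wild-type vehicle 3 at 0.955 with both of its own. These arrays also had the narrowest interquartile ranges, 3.26 and 3.01 log2, against 3.36 to 3.85 on the other arrays. Every comparison below uses at least 1 of them, and counts without both are given beside the main ones.

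**Figure D1:**
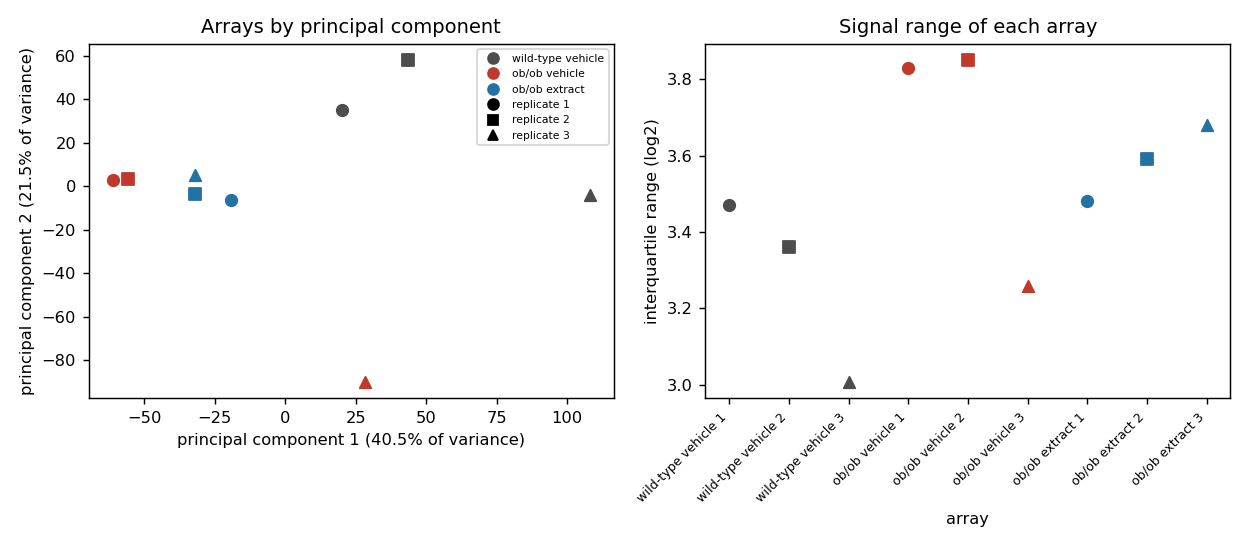
Left, position of each of the 9 arrays on the first and second principal components of all log2 values, which carry 40.5% and 21.5% of the variance; right, the interquartile range of each array in log2. Colour marks the group and symbol shape the replicate; wild-type vehicle 3 and ob/ob vehicle 3 lie away from their groups on the left and have the lowest ranges on the right (3.01 and 3.26).

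*Lep*, the gene mutated in ob/ob mice, was near the bottom of every array (between the 0.694th and 13.4th percentile), at 3.07 ± 0.55 (SD, n = 3) log2 in wild type, 2.98 ± 0.16 in ob/ob vehicle and 2.71 ± 0.17 in ob/ob extract. Liver does not normally express it and the mutation leaves the transcript in place, so these values do not check the genotype labels.

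The first comparison asked how liver of untreated ob/ob mice differed from wild type. Of 20 genes with higher expression in male liver 15 fell, and of 21 with higher expression in female liver 10 rose. The organic anion transporter *Slco1a1* was at 4.86 ± 0.79 log2 in ob/ob vehicle and 16.01 ± 0.30 in wild type (n = 3 each; log2 change −11.15, SE 0.39, adjusted p = 2.94e-07). The steroid dehydrogenase *Hsd3b5* changed by −9.86 (SE 0.33, adjusted p = 2.94e-07). Among the female-biased genes that rose were the cytochrome P450 *Cyp2b9*, from 5.12 ± 0.89 to 16.94 ± 1.14 (change 11.81, SE 0.58, adjusted p = 5.51e-06) and the estrogen sulfotransferase *Sult1e1* (log2 change at least 10.06, SE 0.96, adjusted p = 7.66e-04). The fatty acid translocase *Cd36* went from 8.05 ± 0.36 to 14.72 ± 0.33 (change 6.67, SE 0.27, adjusted p = 1.17e-06). The apolipoprotein gene *Apoa4* rose by 8.30 (SE 0.63, adjusted p = 1.31e-04).

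Among the other genes with the largest rises were the surface protein gene *Ly6d* (8.45), the P450 gene *Cyp2b13* (7.43), the sulfotransferase *Sult2a2* (6.93) and *Themis* (6.73), known for its role in T cell development, with adjusted p between 1.90e-04 and 0.00446. The iron-binding acute phase gene *Lcn2* (7.46, adjusted p = 0.0199) and the metallothionein *Mt2* (7.03, adjusted p = 0.0127) also rose. The call of *Lcn2* was lost without wild-type vehicle 2 or 3 (adjusted p = 0.0785 and 0.0727) and that of *Mt2* without ob/ob vehicle 1 or wild-type vehicle 2 (0.0532 and 0.0663). The largest falls further included the growth factor binding protein gene *Igfbp2* (−7.47), the bile acid synthesis gene *Cyp7b1* (−6.47) and the complement gene *C6* (−6.20). With them were the epidermal growth factor receptor *Egfr* (−5.92), *Serpina1e* (−5.72), the fatty acid elongase *Elovl3* (−5.68) and E-cadherin, *Cdh1* (−4.22). The adjusted p of these falls lay between 2.39e-05 and 0.00385. The complement gene *C8b* fell by 4.47 (adjusted p = 0.0403) and lost its call without wild-type vehicle 1, 2 or 3 (adjusted p = 0.0819, 0.146 and 0.0761), ob/ob vehicle 1 or 2 (0.132 and 0.139) or extract 2 (0.0763).

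For 6 of these 20 genes all 3 values of the lower group lay under the upper end of the middle 95% of olfactory receptor genes, silent in liver, on the same arrays, a comparison chosen after the values were seen. They were *Sult1e1*, *Ly6d*, *Lcn2* and *Themis* in wild type and *Slco1a1* and *Hsd3b5* in ob/ob vehicle. Their lower values are not shown to be above background, so the sizes of their changes are at best lower bounds. *Cyp2b9* and *Sult2a2* in wild type and *Cdh1* in ob/ob vehicle lay under that end on 2 of 3 arrays. The sizes of their changes may also be lower bounds. *Sult1e1* in wild type (3.36 to 3.71 log2) was under the median of those genes (3.78 to 4.50) on all 3 arrays.

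**Figure D2:**
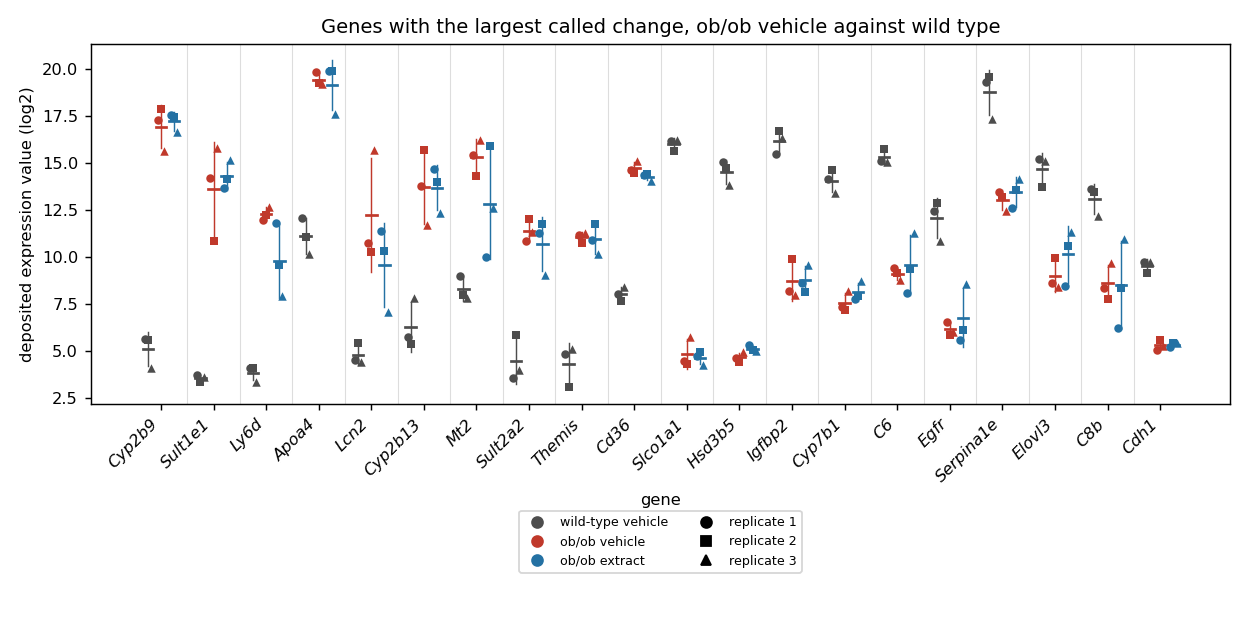
Deposited log2 value (y axis) of the 20 genes with the largest called rises and falls in ob/ob vehicle against wild type (x axis), in each of the 9 mice. Points are mice, horizontal bars group means and vertical lines 1 SD (n = 3); the extract mice sit near the ob/ob vehicle mice for genes such as *Cyp2b9*, *Cd36*, *Slco1a1* and *Cdh1*.

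By gene list, 15 of 20 measured male-biased genes fell and 0 rose (16 and 0 adjusted over the list alone; mean change −3.58, camera adjusted p = 5.35e-21). Of 21 female-biased genes 10 rose and 0 fell (13 and 1 adjusted over the list alone; mean 3.12, adjusted p = 3.07e-11). Both calls held when the inter-gene correlation was estimated (adjusted p = 0.025 with an estimated correlation for each). In the fit without both arrays that stood apart the male-biased call was lost with an estimated correlation (adjusted p = 0.0892) and the female-biased call was not (0.0467).

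In the lipid droplet list 8 of 23 genes rose and 1 fell (9 and 1 adjusted over the list alone), among them the droplet protein gene *Cidea* (5.24, adjusted p = 0.00306), the monoacylglycerol acyltransferase *Mogat1* (3.17, adjusted p = 0.00397) and *Fitm1* (2.34, adjusted p = 0.00795). In the fatty acid oxidation list 7 of 23 rose and 0 fell (14 and 0 adjusted over the list alone), with the pantetheinase *Vnn1* at 4.98, the carnitine carrier *Slc25a20* at 2.35 and the dehydrogenase *Acadm* at 2.32 (adjusted p at most 0.00795). In the de novo lipogenesis list 5 of 18 rose and 1 fell (9 and 1 adjusted over the list alone). The elongase *Elovl6* rose by 5.43 (adjusted p = 0.0117) and *Mlxipl*, which encodes the carbohydrate-responsive factor ChREBP, fell by 3.35 (adjusted p = 0.0267). The call of *Elovl6* was lost without ob/ob vehicle 1 or 2 or wild-type vehicle 2 (adjusted p = 0.0540, 0.0544 and 0.0646), and that of *Mlxipl* without ob/ob vehicle 1, wild-type vehicle 2 or 3 or extract 2 (0.0638, 0.117, 0.0941 and 0.0562). The 3 lists had camera adjusted p of 1.03e-07, 3.44e-12 and 5.63e-05, and these calls did not hold with an estimated correlation (adjusted p = 0.229, 0.267 and 0.553 with an estimated correlation, for lipid droplets, oxidation and lipogenesis). The lipogenesis call was also lost with the interquartile range as a covariate (adjusted p = 0.0867).

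Of 21 measured NRF2 targets and antioxidant genes 8 rose and 0 fell (14 and 0 adjusted over the list alone; mean 1.87, camera adjusted p = 2.39e-13). They included the glutathione transferase *Gsta2* (3.92, adjusted p = 0.00196) and the quinone reductase *Nqo1* (3.49, adjusted p = 0.00326). In the list of drug-metabolising P450 genes, which shares 3 genes with the female-biased list, 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 1.19e-04). *Cyp2c38* rose by 4.08 (adjusted p = 0.00397). Of 24 acute phase genes 6 rose and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 2.48e-05), among them the orosomucoid *Orm3* by 5.66 (adjusted p = 8.22e-04) and the metallothionein *Mt1* by 5.24 (adjusted p = 0.00593). With an estimated correlation these 3 lists had adjusted p = 0.144, 0.267 and 0.395. The acute phase list was highest on ob/ob vehicle 3, and without both arrays that stood apart its adjusted p was 0.0820. The list of cell cycle genes (1 of 22 rose, 2 adjusted over the list alone; mean 0.46, camera adjusted p = 0.00123) and that of oxidative phosphorylation (0 of 28 rose by either adjustment; mean 0.45, camera adjusted p = 0.00642) shifted up by small amounts, with adjusted p = 0.342 and 0.699 with an estimated correlation. The oxidative phosphorylation call was lost with quantile normalization (adjusted p = 0.893) and without wild-type vehicle 3 (adjusted p = 0.274) or ob/ob vehicle 3 (adjusted p = 0.0767). Without the 30% of clusters with the lowest mean that call and the cell cycle call were lost (adjusted p = 0.0845 for both), as without the lowest 50% (0.317 and 0.182). Oxidative phosphorylation was also lost with array weights (0.0790), with the interquartile range as a covariate (0.186) and without both arrays that stood apart (0.444). The other 20 lists had camera adjusted p between 0.321 and 0.959. Some of them were called under alternatives, as were bile acid genes after quantile normalization (adjusted p = 0.00978). Sinusoidal endothelial markers were called with array weights (0.0310), without ob/ob vehicle 3 (0.00267) and without both arrays that stood apart (0.00852). The interquartile range as a covariate called bile acid genes (0.00231), cholesterol genes (0.00726) and clock genes (5.80e-06). These alternatives kept the preset correlation of 0.01. With an estimated correlation over all 9 arrays none of the lists they added was called.

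**Figure D3:**
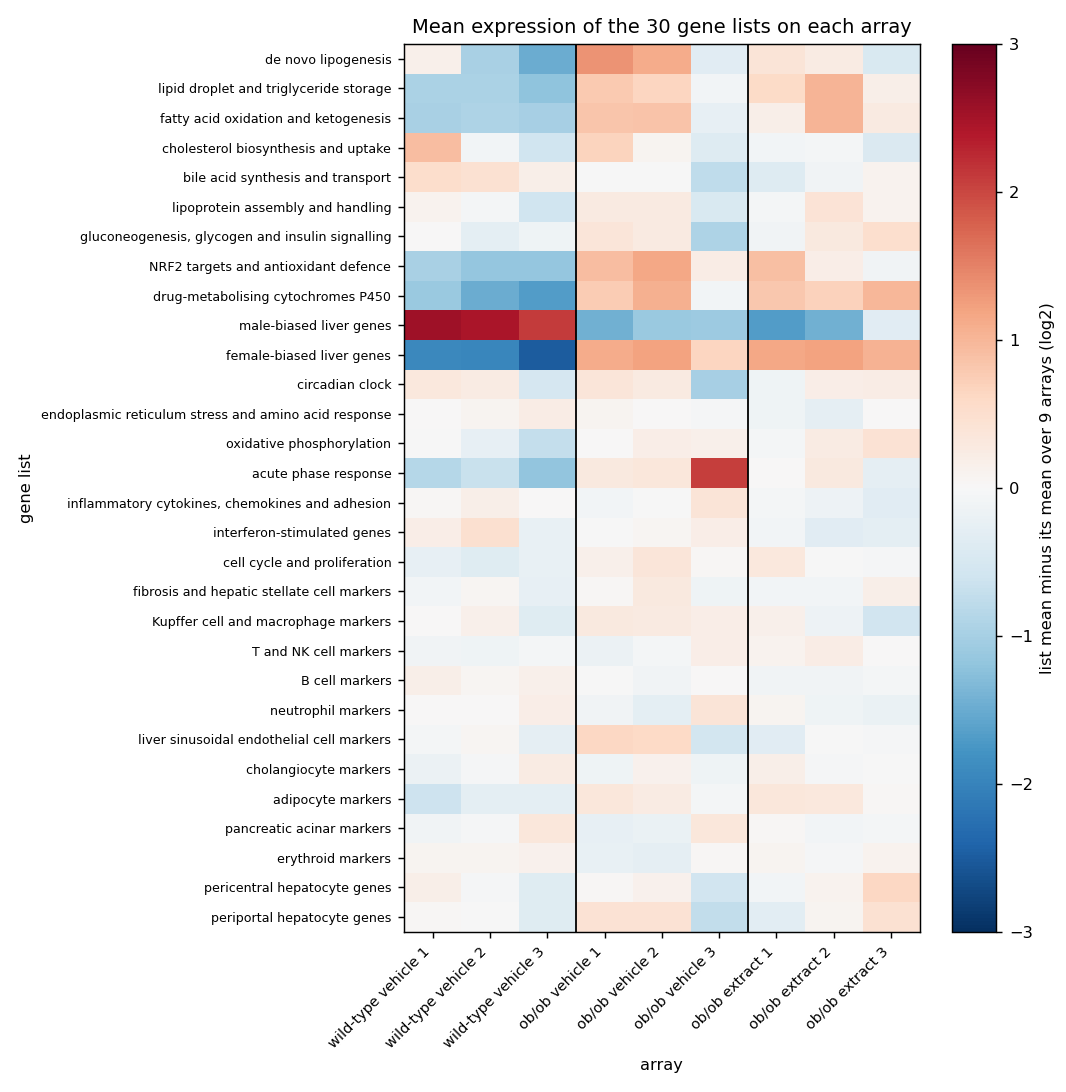
Mean log2 value of each of the 30 gene lists (rows) on each of the 9 arrays (columns), as the difference from that list's mean over the arrays; red is higher and blue lower, and black lines separate the groups. Male-biased genes are high in the wild-type columns and low in all 6 ob/ob columns, and the acute phase list stands out on ob/ob vehicle 3 (2.08 above its mean over arrays).

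In all, limma called 658 of 22206 transcript clusters between ob/ob vehicle and wild type, 507 higher and 151 lower, and 3771 met the design text's criterion. In each of the 658 the groups did not overlap, as in 19.5% of all clusters against 10% for chance. After quantile normalization 290 were higher and 256 lower (53.1% higher, against 77.1% in the deposited values), while subtracting array medians moved the median change of all clusters from −0.06 to 0.06, and from −0.05 to 0.09 for extract against wild type. Leaving out 1 array gave 147 calls without wild-type vehicle 2, 173 and 186 without ob/ob vehicle 1 and 2, and 262 without wild-type vehicle 3. It gave 327 and 404 without extract 2 and 3, 435 without extract 1 and 1679 without ob/ob vehicle 3. The extract arrays are in neither group of this comparison and acted only through the shared spread. Without both arrays that stood apart 1745 were called.

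The second comparison asked what the extract changed in ob/ob liver. With the planned model limma called 0 clusters (smallest adjusted p = 0.593). With array weights it called 106 (79 of them lower, smallest adjusted p = 0.0128), and with the interquartile range as a covariate, an alternative chosen after the data were seen, 1 (0.00390). In the planned model 1433 had an unadjusted p under 0.05, where chance alone would give 1110.3. All of these met the design text's criterion (790 higher, 643 lower). Lower values with the extract and the smallest p were those of the translation elongation factor *Eef1b2* (13.47 ± 0.10 against 15.42 ± 0.18 log2, n = 3; difference −1.95, SE 0.29), the sialyltransferase *St6gal1* (−1.84, SE 0.29), the clock repressor *Nr1d1* (6.28 ± 0.48 against 8.72 ± 0.39; −2.43, SE 0.40) and the heme oxygenase *Hmox1* (8.04 ± 0.29 against 9.42 ± 0.08; −1.38, SE 0.23). *Tubb4b* (−2.08) and *Cmtm3* (−1.42) followed. Higher values were those of *Lonrf3* (1.77, SE 0.35), *Glt1d1* (1.69, SE 0.36), *Safb* (1.27), *Rab27b* (1.22), *Uvssa* (1.19) and *Tmc7* (1.02). In each of these 12 genes the groups did not overlap, which held for 13.6% of all clusters against 10% for chance, and none was past the threshold (adjusted p = 0.593 for each).

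**Figure D4:**
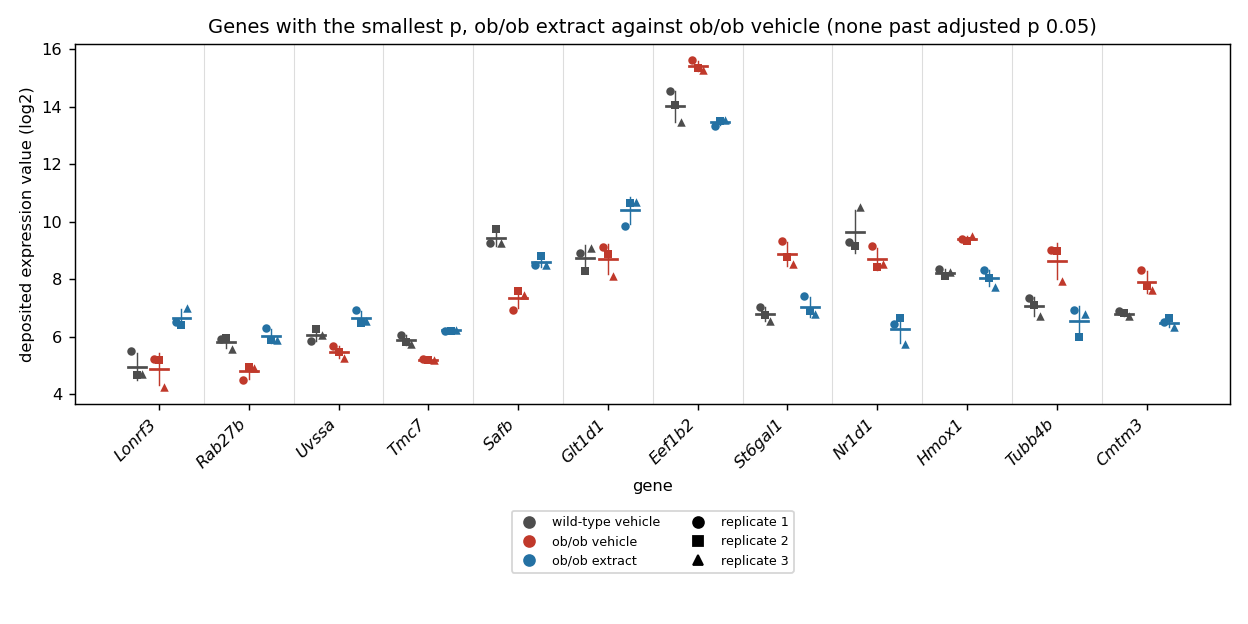
Deposited log2 value (y axis) of the 12 genes with the smallest p in extract against ob/ob vehicle without overlap (x axis), in each of the 9 mice. Points are mice, horizontal bars group means and vertical lines 1 SD (n = 3); none passed the adjusted threshold, and differences between the red and blue means run from −2.43 (*Nr1d1*) to 1.77 (*Lonrf3*).

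Among the genes that differed most between ob/ob vehicle and wild type, *Slco1a1* differed by −0.20, *Hsd3b5* by 0.44, *Cyp2b9* by 0.27, *Cd36* by −0.45, *Themis* by −0.12 and *Cdh1* by 0.04 between extract and ob/ob vehicle. Leaving out 1 array took these to between −0.46 and 0.26 (*Slco1a1*), 0.33 and 0.57 (*Hsd3b5*), −0.37 and 0.73 (*Cyp2b9*), −0.58 and −0.26 (*Cd36*), −0.53 and 0.26 (*Themis*), and −0.08 and 0.17 (*Cdh1*), so the sign of 4 of them depended on single arrays. For *Slco1a1* and *Hsd3b5* both ob/ob groups were within the olfactory receptor range, where a difference cannot be read. Differences of over 2 log2 were those of *Ly6d* (−2.51, SE 0.75), *Lcn2* (−2.65, SE 1.37) and *Mt2* (−2.48, SE 1.15), with adjusted p of 0.707 to 0.790. Single arrays moved these differences. Leaving out 1 array took that of *Lcn2* from −3.65 (without ob/ob vehicle 2) to −0.92 (without ob/ob vehicle 3), that of *Mt2* from −4.00 (without extract 2) to −1.06 (without extract 1) and that of *Ly6d* from −3.54 (without extract 1) to −1.59 (without extract 3). Of the other falls, *Elovl3* (1.14), *Egfr* (0.62), *Cyp7b1* (0.56), *C6* (0.47), *Serpina1e* (0.43) and *Igfbp2* (0.09) lay toward wild type and *C8b* (−0.09) away. Of the other rises, *Sult2a2* (−0.72), *Apoa4* (−0.28) and *Cyp2b13* (−0.04) lay toward it and *Sult1e1* (0.70) away. Whichever array was left out, *Elovl3*, *Cyp7b1* and *Serpina1e* kept their sign. None was called, and the shared ob/ob vehicle arrays favour this direction.

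At the level of gene lists, camera placed 7 of 30 lists lower with the extract and 0 higher. The acute phase list had the smallest adjusted p (0.00176; mean difference −0.90 over 24 genes, 5 of them higher), with the lipopolysaccharide-binding protein gene *Lbp* at −1.13 and the serum amyloid genes *Saa4* at −1.59 and *Saa2* at −4.15. The lists of de novo lipogenesis (mean −0.65 over 18 genes; *Acaca* −1.26, *Acly* −1.29), NRF2 targets (−0.43 over 21; *Hmox1* above, *Gclc* −1.26) and Kupffer cell and macrophage markers (−0.45 over 23; *Cd5l* −2.13, *Adgre1* −1.05, *C1qb* −1.07, with *Cd163* at 1.22) each had an adjusted p of 0.0201. Interferon-stimulated genes (−0.31 over 21; *Xaf1* −1.06; adjusted p = 0.0233), sinusoidal endothelial markers (−0.35 over 16; *Dnase1l3* −0.76; adjusted p = 0.0267) and inflammatory genes (−0.28 over 23; *Cxcl10* −0.97, *Ccl2* −0.79; adjusted p = 0.041) followed. In none of these 7 lists did a single gene pass the threshold over all clusters; adjusted over the list alone 1 did, *Hmox1*. With an estimated correlation all 7 calls were lost (adjusted p = 0.827 with an estimated correlation for each), and each was also lost without at least 1 array. Array weights ended the calls of acute phase and inflammatory genes (0.233 and 0.296), and the interquartile range as a covariate those of interferon-stimulated genes and endothelial markers (0.0554 and 0.0871). Leaving out the lowest 50% of clusters ended those of inflammatory genes (0.531), interferon-stimulated genes and endothelial markers (0.0608 each). The inflammatory call was also lost with the lowest 30% left out (0.109), with only the 2 groups compared (0.0553), with the replicate block (0.0604) and on ranks (0.0675). Among the 23 other lists the adjusted p was 0.0782 to 0.977, and in the list of gluconeogenesis, glycogen and insulin signalling 3 genes were higher adjusted over the list alone: the glycogen synthase *Gys2* (1.02), the glycogen-targeting subunit *Ppp1r3b* and *Foxo1* (1.09). After quantile normalization camera placed that list and the pericentral list higher (adjusted p = 0.0405 and 0.0462), as it did with the interquartile range as a covariate (0.0259 and 0.0317), when clock genes were also called (0.0259). In the fit without both arrays that stood apart neither was called (0.717 and 0.880) and the mean of the gluconeogenesis list turned to −0.09. Leaving out 1 array called the gluconeogenesis list without ob/ob vehicle 1 or 2, wild-type vehicle 3 or extract 1 (0.00565, 0.0409, 0.0362 and 0.00514) and the pericentral list without ob/ob vehicle 1 or 2 or extract 1 (0.0365, 0.0409 and 0.00514). Without ob/ob vehicle 3 the gluconeogenesis list had an adjusted p of 0.544. Cholesterol genes were called with array weights (0.0267), with the replicate block (0.0380) and without ob/ob vehicle 3 or extract 1 (0.00328 and 0.0401). Fatty acid oxidation was called without ob/ob vehicle 3 or extract 2 (0.00545 and 0.0497), P450 genes without ob/ob vehicle 2 (0.0459) and oxidative phosphorylation without extract 1 (0.0230).

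Ob/ob vehicle 3 weighed heavily on this comparison. Without it 51 clusters were called, all lower with the extract, and without both arrays that stood apart 360 were, 312 lower and 48 higher. *Nr1d1* (−2.52, adjusted p = 0.00693), *Eef1b2* (−2.03, adjusted p = 0.00625) and *Hmox1* (−1.34, adjusted p = 0.0314) were then past the threshold. The acute phase list was not (mean −0.31, adjusted p = 0.532). In that fit, which leaves 2 ob/ob vehicle arrays, camera placed lower the lists of lipogenesis (mean −1.18, adjusted p = 2.41e-06), sinusoidal endothelial markers (−0.74, 2.41e-06), NRF2 targets (−0.71, 3.32e-04), cholesterol genes (−0.57, 0.00281), Kupffer cell markers (−0.48, 0.00775) and fatty acid oxidation (−0.37, 0.00775). None of these 6 calls held with an estimated correlation (adjusted p = 0.673, 0.478, 0.673, 0.778, 0.673 and 0.778 with an estimated correlation).

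The third comparison set extract-treated ob/ob mice against wild type. Of the clusters called between untreated ob/ob mice and wild type, 179 of 507 higher and 56 of 151 lower ones were called again. *Cyp2b9* was higher by 12.09 (SE 0.58, adjusted p = 4.36e-06), *Sult1e1* by at least 10.76 (adjusted p = 6.02e-04) and *Apoa4*, at the array maximum on extract 1, by at least 8.03 (adjusted p = 2.20e-04). *Cyp2b13* was higher by 7.39 (adjusted p = 0.00548), *Themis* by 6.61 (adjusted p = 2.86e-04), *Cd36* by 6.23 (adjusted p = 2.39e-06) and the acyl-CoA thioesterase *Acot3* by 7.27 (adjusted p = 0.00508). *Slco1a1* was lower (change −11.35, SE 0.39, adjusted p = 2.84e-07), *Hsd3b5* changed by −9.42 (adjusted p = 2.84e-07), *Igfbp2* by −7.38 (adjusted p = 1.47e-04) and *Cdh1* by −4.19 (adjusted p = 2.78e-05). *Nr1d1* was lower than in wild type (−3.37, adjusted p = 0.00307), whereas between ob/ob vehicle and wild type it differed by −0.94 (adjusted p = 0.266). The difference between these changes is the comparison of extract with ob/ob vehicle above. For *Sult1e1*, *Themis* and *Ly6d* in wild type and *Slco1a1* and *Hsd3b5* with the extract, 5 of the 20 genes of the naming rule's first part, the lower group was again within the olfactory receptor range, so these sizes are at best lower bounds. In wild type *Cyp2b9* and *Sult2a2* were within it on 2 of 3 arrays, so their sizes may be lower bounds too.

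In this comparison 11 of 20 male-biased genes fell (16 adjusted over the list alone; camera adjusted p = 2.94e-24) and 9 of 21 female-biased genes rose (13 adjusted over the list alone; adjusted p = 1.83e-13), with adjusted p = 0.0172 for both with an estimated correlation. The lists of fatty acid oxidation (6 of 23 rose; 13 adjusted over the list alone), lipid droplets (5 of 23; 13), NRF2 targets (4 of 21; 9) and drug-metabolising P450 genes (6 of 17; 7) were higher, with camera adjusted p of 2.46e-13, 3.21e-11, 1.52e-08 and 2.89e-06 and adjusted p = 0.229, 0.135, 0.229 and 0.195 with an estimated correlation. In the oxidation list *Vnn1* rose by 4.43 (adjusted p = 0.00954), a call lost without extract 1 or 2 or wild-type vehicle 2 (adjusted p = 0.0538, 0.0666 and 0.0605). Lists of oxidative phosphorylation (camera adjusted p = 2.87e-05), cell cycle (0.00939), de novo lipogenesis (0.014), gluconeogenesis, glycogen and insulin signalling (0.0235) and acute phase genes (0.0488) were also higher and interferon-stimulated genes lower (0.0148); with an estimated correlation their adjusted p ran from 0.44 to 0.689. After quantile normalization the calls of oxidative phosphorylation, lipogenesis, gluconeogenesis and acute phase genes were lost (adjusted p = 0.0917, 0.104, 0.205 and 0.189). Median subtraction ended those of lipogenesis, gluconeogenesis and acute phase genes (0.0508, 0.0824 and 0.0930). Filters on the lowest 30% and 50% of clusters ended these (0.0740, 0.114 and 0.194 with 30%; 0.166, 0.331 and 0.617 with 50%) and that of cell cycle genes (0.0870 and 0.146). The acute phase call was also lost with only the 2 groups compared (0.0535), array weights (0.0671), the replicate block (0.0929), ranks (0.196) and without both arrays that stood apart (0.124). Ranks ended the gluconeogenesis call (0.0543), the fit without both arrays that of lipogenesis (0.0809), and the interquartile range as a covariate both (0.755 and 0.643). Leaving out 1 array ended the call of lipogenesis (wild-type vehicle 2 or 3 or extract 1, adjusted p = 0.0789, 0.0799 and 0.0910) and of gluconeogenesis (wild-type vehicle 2 or extract 2 or 3, 0.0938, 0.0541 and 0.121). It also ended the call of cell cycle genes (wild-type vehicle 2 or extract 1, 0.0654 and 0.0910), of interferon-stimulated genes (wild-type vehicle 1 or 2 or extract 2, 0.0769, 0.188 and 0.0617) and of acute phase genes (ob/ob vehicle 2 or 3, wild-type vehicle 1 or 3 or extract 2, 0.0533, 0.0532, 0.0868, 0.111 and 0.0986). The other 18 lists had adjusted p between 0.0909 and 0.901. Of these, quantile normalization called cholesterol genes (adjusted p = 0.00779), bile acid genes (0.0436) and endoplasmic reticulum stress genes (0.0237). The fit without both arrays that stood apart called cholesterol genes (5.33e-04) and Kupffer cell markers (0.0421), as did leaving out the lowest 50% of clusters (0.0175 each). Leaving out wild-type vehicle 3 called cholesterol genes (6.66e-04). The interquartile range as a covariate called cholesterol (2.23e-05), bile acid (0.00715), clock (0.00735) and sinusoidal endothelial genes (0.00169). These alternatives kept the preset correlation of 0.01. With an estimated correlation over all 9 arrays none of the lists they added was called.

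Limma called 287 clusters between extract and wild type, 217 higher and 70 lower (75.6% higher; 153 and 97, 61.2%, after quantile normalization), and 3115 met the design text's criterion. Independent lists would share 4.95 higher and 0.476 lower clusters with those of untreated ob/ob mice, against the 179 and 56 above. Part of this overlap may come from the wild-type arrays that both comparisons share. Across genes the changes correlated at r = 0.812, beside 0.459 on average for simulated unchanged groups (95% of simulations −0.488 to 0.944), and the covariance exceeded the simulated mean by 0.298 (0.384 against 0.0865), above 95% of the simulations (−0.0548 to 0.343), whereas r was within them. Genes are not independent replicates. Leaving out 1 array gave 77, 105 and 173 calls without extract 2, 1 and 3, 97 and 153 without wild-type vehicle 2 and 3, and 598 without ob/ob vehicle 3. Ob/ob vehicle 3 is in neither group of this comparison and acted only through the shared spread. Without both arrays that stood apart 595 clusters were called.

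Whether the extract moved genes back toward wild type was examined over all 22206 clusters. The changes from wild type to ob/ob vehicle and from ob/ob vehicle to extract correlated across genes at r = −0.414. Groups that did not differ but shared the ob/ob vehicle arrays gave −0.442 on average in 1000 simulations (95% between −0.943 and 0.567). These simulated groups also lacked the difference between ob/ob vehicle and wild type that the data held. If the extract's changes are unrelated to that difference, it widens the first set of changes and moves r toward 0. A partial reversal by the extract would instead make the covariance more negative. The observed and simulated r are therefore not on the same scale, and their closeness does not decide. Same-numbered arrays were taken as unpaired. The covariance was −0.125 beside a simulated −0.0861, a difference of −0.0393, within the range of the simulations (−0.387 to 0.0638). Of the 658 clusters called in the first comparison 528 (80.2%) had the opposite sign in the second; in 50 simulations in which the extract changed nothing the median was 62.9% (95% between 19.3% and 87.4%). These simulations called a median of 1209.5 clusters, so their share was taken over a larger set than the 658. For the 507 clusters higher in ob/ob vehicle the median change was 1.95 and the median difference with the extract −0.45, and for the 151 lower ones −2.01 and 0.46. The 3 ob/ob vehicle arrays were too few to split between the comparisons.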

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

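Without both arrays that stood apart and the interquartile range as a covariate were alternatives chosen after the data were seen; the others were planned. None of the lists or named genes that passed the threshold changed sign under any alternative run. Counts have no sign to change, but their balance of higher and lower calls did move. For extract against ob/ob vehicle array weights gave 27 higher and 79 lower calls, and the interquartile range as a covariate 1 higher and 0 lower. The quantile normalization, median subtraction, intensity trend, 30% filter, rank and cluster-mean alternatives kept the totals of calls, clusters by the criterion and lists within 1.5 times. Quantile normalization moved the calls by direction further for ob/ob against wild type, from 507 to 290 higher and from 151 to 256 lower. With the interquartile range as a covariate 541 were higher and 312 lower there, and 177 and 147 for extract against wild type. With array weights limma called 2137 clusters for ob/ob against wild type (5702 by the design text's criterion), 106 for extract against ob/ob vehicle (3741) and 796 for extract against wild type. Without the empirical Bayes step the counts were 31, 0 and 16, and with only the 2 groups compared ob/ob against wild type had 207. Leaving out the lowest 50% of clusters gave 817 by the criterion and 4 lists for extract against ob/ob vehicle, with fewer clusters tested. An estimated inter-gene correlation left 2, 0 and 2 lists. Without both arrays that stood apart the calls were 1745, 360 and 595, and 3380 by the criterion for extract against ob/ob vehicle; with the interquartile range as a covariate that comparison had 1 call and 2928 by the criterion. The causes of these differences were not tested beyond the fewer arrays or clusters that the settings use.

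Leaving out each array in turn gave 147 to 1679 calls for ob/ob against wild type. The count was 147 without wild-type vehicle 2 and 1679 without ob/ob vehicle 3. For extract against ob/ob vehicle it gave 0 to 51 (51 without ob/ob vehicle 3), and for extract against wild type 77 to 598 (77 without extract 2 and 598 without ob/ob vehicle 3). An array outside both groups of a comparison changes only the shared spread there, as ob/ob vehicle 3 did for extract against wild type. By the design text's criterion the ranges were 2814 to 5187, 1025 to 2452 and 2179 to 4057, and for lists 9 to 10, 1 to 10 and 8 to 12. Each of the 7 lists called for extract against ob/ob vehicle was lost without some array. These were acute phase without ob/ob vehicle 3 (adjusted p = 0.51), lipogenesis without ob/ob vehicle 1 or 2 or extract 3 (0.262, 0.149, 0.228), NRF2 targets without the same arrays (0.0640, 0.309, 0.331), and Kupffer cell markers without ob/ob vehicle 1 or extract 3 (0.0562, 0.228). The others were endothelial markers without ob/ob vehicle 1 or 2 or extract 1 or 3 (0.356, 0.309, 0.119, 0.0774), interferon-stimulated genes without ob/ob vehicle 3 or extract 2 or 3 (0.126, 0.0923, 0.116), and inflammatory genes without ob/ob vehicle 3, wild-type vehicle 1 or extract 2 or 3 (0.544, 0.0507, 0.0579, 0.228). Of 56 called genes covered by the naming rule in ob/ob against wild type 34 stayed past the threshold whichever array was left out, and of 45 in extract against wild type 27 did. The opposition correlation lay between −0.605 and −0.356 over 16 alternatives, with a two-sided share of simulations of at least 0.572. Because those simulations held no ob/ob difference, that share does not decide whether the extract opposed it.

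With the replicate block the calls were 579, 0 and 283, the criterion gave 3735, 1444 and 3212, and the lists numbered 10, 7 and 11. The opposition correlation was −0.414, which the block could not move, since each group holds every replicate number once. The block ended the calls of inflammatory genes (extract against ob/ob vehicle, adjusted p = 0.0604) and acute phase genes (extract against wild type, 0.0929), added cholesterol biosynthesis (extract against ob/ob vehicle, 0.038), and changed 10 calls among the genes of the naming rule. Between ob/ob vehicle and wild type these were *Fbp1* (0.0749), *Birc5* (0.0731), *Rgs5* (0.0582) and *Cyp1a2* (0.0650), no longer called, and *Pcx* (0.0182), *Hyou1* (0.0228) and *Mmp12* (0.0178), then called. Between extract and wild type *Foxo1* (0.0606) was no longer called and *Elovl6* (0.0467) and *Cidec* (0.0265) were. The block changed no other call of those genes and lists. Signal over background is not known here, so what limits dim genes could not be assessed.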

Other observations

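Apart from the one on testis genes, tests of the acute phase, amplified family and muscle patterns were chosen after the values were seen. For that one the prediction was written before, but the gene lists it used were written after. The counts over other splits were planned. The condition that *Ckm* and *Eno3* also be high was added to the muscle test after their values were seen.

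In some lists that the planned test did not call between ob/ob vehicle and wild type, single genes were past the threshold. Of 22 bile acid genes 3 rose and 3 fell. *Slco1a1* and *Cyp7b1* fell, as given, and the transporters *Abcc4* (3.35, limma adjusted p = 0.0191) and *Abcb4* (1.46, adjusted p = 0.0109) rose. In the adipocyte list 3 of 14 genes rose and 0 fell, 8 of the 14 lay lower, and camera gave an adjusted p of 0.634. The adipogenic receptor *Pparg* rose by 3.51 (adjusted p = 0.00922), the fatty acid binding protein *Fabp4* by 1.89 (adjusted p = 0.0235) and *Cidec* by 4.61 (adjusted p = 0.0402), and the adipocyte coat protein *Plin1* was at 3.91 against 4.81 log2 (adjusted p = 0.0839). In the lipoprotein list 1 of 18 rose and 1 fell. *Apom*, which encodes an apolipoprotein of high-density lipoprotein, fell by 3.94 (adjusted p = 0.00397). In the periportal list 1 of 14 genes rose, *Aldh1b1*, by 2.46 (adjusted p = 0.00724). Of 23 macrophage markers 1 fell, the scavenger receptor *Cd163* (change −1.53, adjusted p = 0.0417), and in the extract group it was 1.22 above ob/ob vehicle (adjusted p = 0.707). Without wild-type vehicle 2 the calls of *Abcc4* (adjusted p = 0.0910), *Abcb4* (0.0604), *Fabp4* (0.0767) and *Cd163* (0.156) were lost, and without ob/ob vehicle 1 likewise (0.0816, 0.0516, 0.0515 and 0.142). Without ob/ob vehicle 2 the first 3 were lost (0.0822, 0.0529 and 0.0773), without wild-type vehicle 3 *Abcc4* and *Cd163* (0.0576 and 0.0706), and *Cd163* also without wild-type vehicle 1 (0.0700) or any extract array (0.0658 to 0.0751). The call of *Cidec* was lost without ob/ob vehicle 1 or 2 (0.148 and 0.127), wild-type vehicle 1, 2 or 3 (0.0812, 0.123 and 0.0972) or extract 2 (0.0574).

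Some lists had a median, mean and camera direction that differed in sign, none of them called in the planned test. Between ob/ob vehicle and wild type the T and NK cell markers had a median of −0.23 and a mean of 0.09, with *Themis* the 1 gene that rose, and camera placed the list lower (adjusted p = 0.321). The gluconeogenesis list (median −0.16, mean 0.04), adipocyte markers (−0.11 and 0.59) and inflammatory genes (−0.02 and 0.03) had the direction of their mean, and cholesterol genes (0.16 and 0.04) were placed lower. Between extract and ob/ob vehicle this held for male-biased genes (−0.02 and 0.07), periportal genes (−0.06 and 0.03) and pancreatic markers (−0.07 and 0.01), placed higher, and for fatty acid oxidation (−0.08 and 0.00), placed lower. Between extract and wild type it held for bile acid genes (0.06 and −0.52), T and NK cell markers (−0.08 and 0.22), cholangiocyte markers (−0.00 and 0.02) and erythroid markers (0.05 and −0.06), all placed lower.

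On wild-type vehicle 3, the array with the narrowest interquartile range (3.01 log2), 4 genes picked after their values were seen lay far from the other wild-type arrays. *Fasn* was at 9.56 log2 against 13.42 and 12.19 in the other wild-type mice, *Thrsp* at 13.26 against 17.73 and 16.29, *Angptl8* at 5.65 against 11.95 and 9.87, and *Igfbp1* at 12.16 against 6.33 and 8.24.

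The lower acute phase list with the extract rested on 1 mouse. *Saa2* was at 18.75 log2 on ob/ob vehicle 3 against 10.61 and 11.81 on the other ob/ob vehicle arrays and 7.84 to 11.41 on the extract arrays. *Lcn2* was at 15.71 against 10.77 and 10.25. Without that array the list's mean difference went from −0.90 to −0.31, leaving 34.5% of it, and from −0.90 to −1.20 or −1.18 without ob/ob vehicle 1 or 2. The narrow signal range of that array is argued against: the list's mean deviation there (1.76) was at percentile 100 of 10000 random lists of like expression (95% between −0.898 and 0.00918). An effect of the extract stays open, since without ob/ob vehicle 3 camera gave an adjusted p of 0.51. An inflammatory state of that mouse may account for most of the pattern.

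The arrays that stood apart shared high values of gene families that are amplified in the mouse genome and used in germ cells (*Speer4*, *Btbd35f* and predicted genes of the Y chromosome). Over 70 clusters the median rise over the rest of the group was 2.27 log2 on ob/ob vehicle 3 and 1.97 on wild-type vehicle 3. Single-copy testis genes (19 clusters) had a median rise of at most 8.59% of that. The amplified families were picked for their rise, which favours a small share, so this share does not decide on testis RNA. The families rose by at least 1.31 log2 more than olfactory receptor genes of the nearest level, also silent in liver. A weaker signal that lifts all dim genes stays open, and so does genomic DNA in the labelled material. The amplified families were picked for their rise, so their excess over olfactory receptor genes decides neither. Of families not picked for it, keratin-associated genes rose by 0.13 and 0.24 log2 more than all 1091 olfactory receptor clusters on ob/ob vehicle 3 and wild-type vehicle 3, and defensins by 0.12 and −0.17. The olfactory receptor clusters themselves rose by 0.58 and 0.66, whereas the single-copy testis genes, 19 clusters near the floor, changed by 0.20 and −0.08. DNA and the copies each probe matches were not measured, and no biological explanation was tested.

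Wild-type vehicle 2 carried skeletal muscle transcripts: *Myh2* was at 13.04 log2 against 4.25 and 4.41 in the other wild-type mice, *Acta1* at 12.04 against 4.72 and 4.68 and *Myh4* at 10.83 against 4.09 and 3.47, genes picked after their values were seen. Of 20 muscle genes 85% rose by over 1 log2, as muscle collected with the liver would give, but *Ckm* and *Eno3*, abundant in mature muscle, were higher by 0.61 and 0.64, so this source stays open. The pattern of the other arrays that stood apart is argued against, since the amplified families there were 0.01 log2 above wild-type vehicle 1. An ob/ob array under a wild-type label is argued against by the male-biased list, whose mean was 0.13 above that of the other wild-type arrays and 3.64 above that of the 6 ob/ob arrays. No biological explanation was tested.

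Each comparison of 3 against 3 arrays allows 10 splits, too few for a share under 0.05. For ob/ob against wild type the real split gave 658 calls and the highest other 0 (1 split as large, the real one included), 3771 against 4150 by the design text's criterion (2 as large). For lists it gave 10 against 12 (3 as large). The split with 4150 put ob/ob vehicle 1 and 2 with wild-type vehicle 1 against the rest, so it placed both arrays that stood apart on 1 side. The blocked counts of the real split were 3735 by the criterion and 10 lists, and no other split was run with the block. Without the block, the others among the 4 splits that part all 3 same-number pairs gave at most 0 calls, 1277 by the criterion and 9 lists. For extract against ob/ob vehicle the values were 0 calls against 0 (10 as large), 1433 against 1871 (3 as large) and 7 against 15 lists (8 as large). The split with 1871 put ob/ob vehicle 1 and 2 with extract 3 against the rest, and 15 lists came from that split and from 2 others. For extract against wild type they were 287 against 0, 3115 against 1680 and 12 against 9 lists (1 as large for each).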
